A study of Mus musculus with 2 samples.

How the data were processed

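H3K27me3 was measured by chromatin immunoprecipitation and sequencing in 2 biological replicates of mouse neural tube at 12.5 days of gestation, pooled from 120 and 88 embryos, with a fragment size range of 300 to 500 bp per the labels. The material analysed was the peak lists the authors deposited on mm10: 1 list per replicate, 1 list called on both replicates together, and a replicated list derived from the other 3, per the deposited notes. Every one of the 31216 peaks in the replicated list was also in the list of both replicates. The rule for keeping a peak there is not given in the sources used here. Of the replicated peaks, 21643 (69.3%) overlapped a peak in each single-replicate list, 5242 in replicate 1 only, 3493 in replicate 2 only and 838 in neither, so overlap of the single lists was not the whole of that rule.

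Per the deposited notes, the peaks of replicate 1 came from its filtered alignments with 2 further input files, those of replicate 2 from its filtered alignments with 1 of those same files, and the pooled peaks from both alignments with both files. The content of those files, the aligner, the peak caller and its threshold are not given in the sources used here. The replicates therefore differed in what stood behind their peak calls as well as in the sample. The signal value of each peak was the authors' own, and what it is relative to is not stated; it served only to rank or filter peaks within a list and to describe shared peaks. The −log10 p-value and −log10 q-value of each peak were also the authors'. The lists were permissive: 46.0% of the peaks of replicate 1, 46.8% of those of replicate 2 and 9.58% of the replicated peaks had a −log10 q under 2. Read counts and depth were not analysed here, so a region without a peak may lie under the threshold of the caller, and the 2 replicates' numbers of peaks are no measure of the amount of the mark. Such lists give no scale on which the height of the mark can be compared between replicates.

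Gene records came from GENCODE release M21 and sequence from GRCm38, the assembly of mm10. The peaks of all 20 chromosomes used lay within the lengths of that reference. Protein-coding genes of chromosomes 1 to 19 and X were used, 1 record for each of 21728 symbols; 27 symbols were held by more than 1 gene. Chromosome Y and unplaced sequences were left out, which removed 1 peak from the pooled list and none from the others. A gene was called marked when a peak shared at least 1 bp with the 1 kb either side of the 5′ end of its record. The covered share of a gene was the percentage of the 2.5 kb either side of that end lying in peaks, computed in each replicate's list, with its mean and SD over the 2 replicates. For Hox genes it was also computed over the gene record with 1 kb either side. A share of 0 means that no peak was listed. A promoter was called CpG-rich when the 500 bp either side had a GC fraction of at least 0.5 and an observed over expected CpG ratio of at least 0.6, which held for 9724 genes.

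The 21 gene lists, 23 gene families and the tests were fixed before the data were examined. Of the list members, 3 imprinted genes were not found among protein-coding genes. The named genes were also chosen by a rule fixed at that point: the Hox genes, up to 3 marked members of each list with the highest mean covered share and 2 with the lowest, the genes with a 5′ end in the 15 widest domains, and a fixed set of regulators and reference genes. Other genes named are said to be chosen after their values were seen. Several genes stand in more than 1 list.

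Each list or family was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over all 44, at an adjusted p of 0.05, and again among CpG-rich promoters. Neural regulators (the progenitor and spinal neuron subtype lists) were compared with non-neural regulators (the heart, muscle, endoderm, blood, limb and kidney lists) by the same test, with a permutation test of their covered shares that was not planned, and Hox paralog groups 1 to 9 with 10 to 13 by a two-sided permutation test with 100000 resamples of the mean covered share. The features of the genome and the overlap of the replicates were set against 100 circular shifts of the peaks along their chromosomes, leaving out the first 3 Mb; shifted peaks could fall in other assembly gaps. The rank of X among 20 chromosomes had a smallest two-sided p of 0.1; the plan made before the data were examined gave 1 in 20, which is the one-sided value of 0.05. Genes lie in clusters and are not independent replicates, so p-values over genes describe these 2 samples. Wilson and Newcombe intervals cover counting error only.

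The calls of marked promoters and of lists were run on simulated data. There 200 of 200 planted promoters were recovered among 21728 genes, and 0 of 100 random lists of 30 genes were called. The planted peaks lay on 5′ ends, so recovery followed from the rule for a marked gene. The simulated peaks were fewer than those analysed, and the random lists were not drawn as clustered families. The simulation therefore checked the code and gives no rate of false calls for these data. The alternatives were the pooled peak list, each replicate alone, the replicated peaks at or above the median signal, a −log10 q of at least 3, promoter windows of 500 bp and 2.5 kb, at least 25% of the window covered, any annotated transcript start, CpG-rich promoters only, other overlaps and numbers of peaks for the replicates, bins of 1 kb and 100 kb, other Hox windows and groups, and joining distances of 1 kb and 5 kb. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.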

Results

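H3K27me3, the trimethylation of lysine 27 of histone H3 that is deposited by Polycomb repressive complex 2, was mapped by chromatin immunoprecipitation and sequencing in the neural tube of mouse embryos at 12.5 days of gestation. At this stage the tube holds dividing progenitors arranged in domains along its dorsoventral axis and the young neurons born from them. The series held 1 group of 2 biological replicates. Replicate 1 was made from the neural tubes of 120 embryos and replicate 2 from those of 88 embryos, both of the B6NCrl strain with the sexes pooled. Read depth was unknown, since the values analysed were peaks. Replicate 1 had 74879 peaks covering 31.1 Mb and replicate 2 had 49432 peaks covering 25.9 Mb. The authors' replicated list, which draws on both replicates and is the main peak set here, held 31216 peaks covering 27.7 Mb, or 1.08% of chromosomes 1 to 19 and X. There was no other antibody, tissue or stage in the series, so the comparisons below are between genes and regions within the tissue and between the replicates. All coordinates are mm10.

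The mark lay at the promoters of a minority of genes. Of 21728 protein-coding genes, 3668 had a peak within 1 kb of the 5′ end of the gene record, a share of 16.9% (95% Wilson interval 16.4% to 17.4%, counting error only). These are called marked genes. A gene said to hold no peak had none within 2.5 kb of its 5′ end in either single-replicate list. Promoters took 15.1% of the covered bases, against 1.73% when the peaks were shifted along their chromosomes, an 8.75-fold excess. Exons outside promoters took 10.1% against 3.61%. Intergenic sequence took 39.1% against 57.1%. These differences had a two-sided permutation p of 0.02, the smallest that 100 shifts can give. Introns took 35.6% against 37.6%, which did not pass the test (permutation p = 0.16). The promoter share was 12.8% in replicate 1 and 14.1% in replicate 2. Promoters rich in CpG dinucleotides were marked in 1933 of 9724 cases (19.9%) and the other promoters in 1735 of 12004 cases (14.5%). Single-replicate lists gave 4572 marked genes in replicate 1 and 3847 in replicate 2, of which 3366 were marked in both.

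The Hox clusters, whose genes set position along the body axis and are used in the order of their places in the cluster, were divided sharply. The 12 genes of paralog groups 10 to 13 were covered by peaks over 89.2% ± 11.7 (SD across genes, n = 12) of the gene record with 1 kb either side. The 27 genes of groups 1 to 9 were covered over 10.96% ± 19.4 (SD across genes, n = 27). The difference of 78.2 percentage points had a two-sided permutation p of 2e-05, the smallest that 100000 resamples can give. The test treated the genes as exchangeable, although neighbours in a cluster are not independent and some records overlap. This p is therefore likely too small. With the peaks of replicate 1 alone the means were 80.3% and 12.68%, a difference of 67.6 percentage points. With those of replicate 2 alone they were 81.1% and 6.94%, a difference of 74.2. All 12 genes of the posterior groups had a marked promoter, and their covered shares ran from 64.9% at Hoxa10 to 100% at Hoxb13. In the anterior groups 16 of the 27 records held no replicated peak, among them Hoxa1 to Hoxa7, Hoxb2 to Hoxb7, Hoxc4, Hoxd3 and Hoxd4.

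Some anterior genes stood apart from that division. Hoxb1, at the far 3′ end of its cluster on chromosome 11 (96365752 to 96368256) and known for its use in the hindbrain, was covered over 24.7% ± 10.1 (SD, n = 2) of its record in the single-replicate lists, and Hoxd1 on chromosome 2 (74762980 to 74765142) over 35.1% ± 9.10 (SD, n = 2). Genes of group 9 held intermediate shares that differed by cluster. Hoxd9 was covered over 63.8% ± 0.899 (SD, n = 2), Hoxc9 over 33.6% ± 18.3 (SD, n = 2), Hoxa9 over 17.1% ± 7.64 (SD, n = 2) and Hoxb9 over 13.9% ± 9.82 (SD, n = 2). Some gene records overlap their neighbours, so that a share can belong to more than 1 gene: the record of Hoxc5 begins between the 5′ ends of Hoxc10 and Hoxc9, and 27.9% of it was covered by the replicated list.

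**Figure D1:**
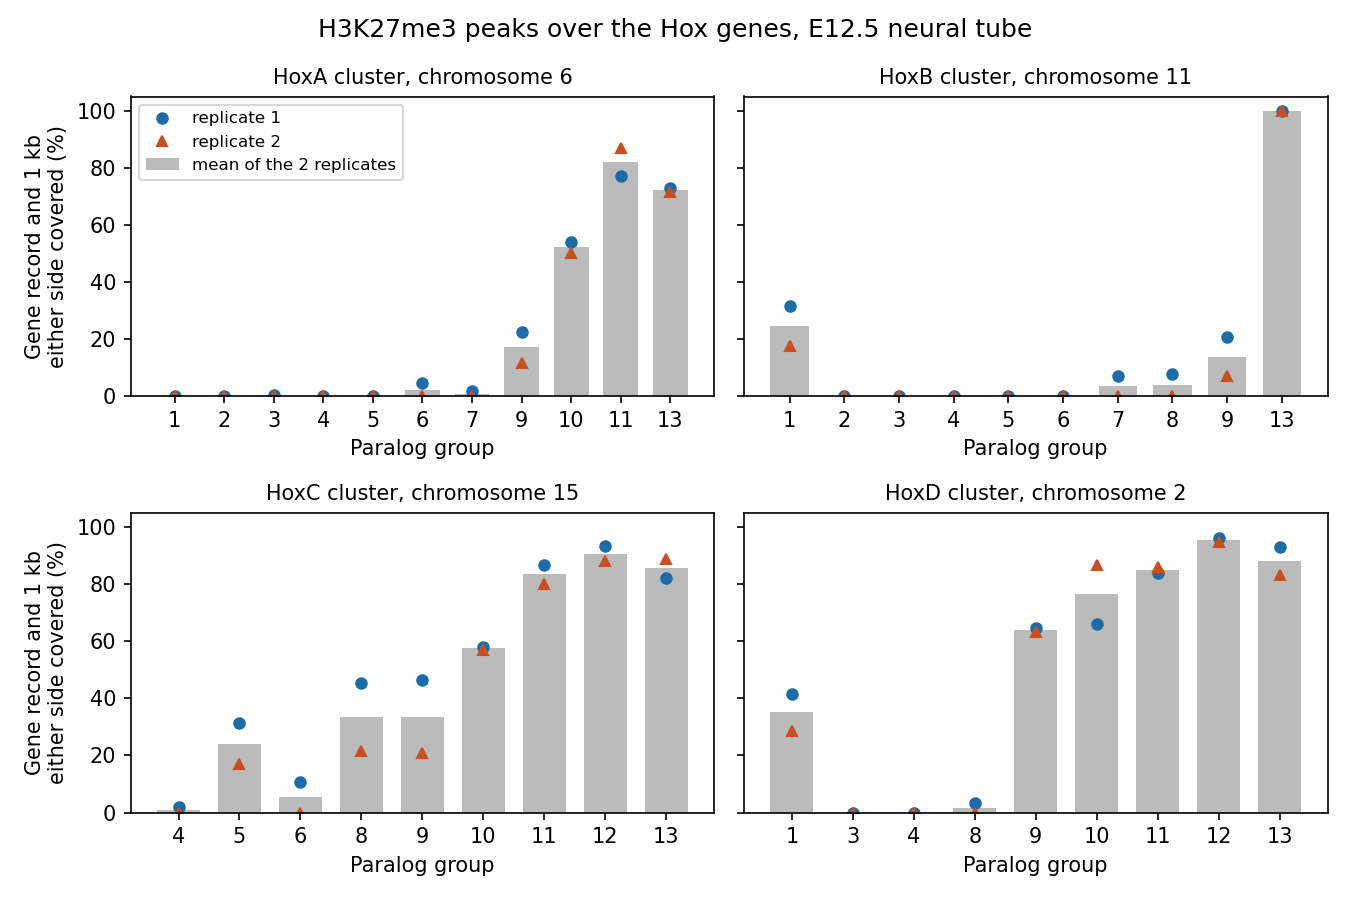
Share of each Hox gene record with 1 kb either side that was covered by peaks (vertical axis, %) by paralog group (horizontal axis) in the 4 clusters; bars are the mean of the 2 replicates and symbols are the replicates. Groups 10 to 13 lie above 50% in both replicates, from Hoxa10 at 54.2% and 50.1% up to Hoxb13 at 100% in both, and most genes of groups 2 to 7 lie at 0.

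Regulators of neural tube patterning were mostly marked in the neural tube taken as a whole. The tissue was pooled, so a peak does not tell which domains or cells carried the mark, or whether they used the gene. Of 33 neural tube progenitor regulators 31 were marked (93.9%, against 16.8% of other genes, Fisher's exact test, adjusted p = 4.11e-21). Most of them are transcription factors and signals that divide the tube into dorsoventral domains. The list also holds more broadly used progenitor genes such as Sox2, Sox3 and Hes1. Olig2, needed for motor neuron progenitors, was covered over 100% ± 0 (SD, n = 2) of the 2.5 kb either side of its 5′ end. Nkx6-2 was likewise at 100% ± 0 (SD, n = 2) and Olig1 at 99.3% ± 0.933 (SD, n = 2). The floor plate factor Foxa2 stood at 99.2% ± 1.10 (SD, n = 2), the ventral signal Shh at 94.9% ± 3.10 (SD, n = 2) and Nkx2-2, of the most ventral neural progenitors, at 93.2% ± 0.650 (SD, n = 2). Pax6 stood at 83.3% ± 7.30 (SD, n = 2), the dorsal factor Pax7 at 73.3% ± 2.02 (SD, n = 2) and Pax3 at 52.4% ± 0.311 (SD, n = 2). Shares varied among the other members: Sox2, the general neural progenitor factor, stood at 19.4% ± 6.84 (SD, n = 2), and the proneural genes Ascl1 and Neurog2 at 26.98% ± 10.2 and 63.1% ± 9.53 (SD, n = 2). The 2 progenitor regulators without a mark were Hes1, a target of Notch signalling, at 15.04% ± 2.71 (SD, n = 2), and Sox3, with no peak in either replicate. Hes1 was marked with the peaks of replicate 1 alone and with a promoter window of 2.5 kb, and Sox3 with the pooled list. Ascl1 was not marked with a window of 500 bp or when at least 25% of the window had to be covered, nor Pax3 with the peaks at or above the median signal.

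Spinal neuron subtype regulators gave a similar share, with 35 of 38 marked (92.1%, Fisher's exact test, adjusted p = 5.77e-23). Gata2, used in V2b interneurons, and Mnx1, of motor neurons, were covered over 100% ± 0 (SD, n = 2), and Nkx2-9 over 99.4% ± 0.848 (SD, n = 2). Isl1, also of motor neurons, stood at 62.5% ± 13.1 (SD, n = 2), and Phox2b, of visceral motor neurons, at 80.8% ± 9.52 (SD, n = 2). The members without a mark were Foxp1, at 0 in both replicates, Foxp2, at 7.77% ± 10.99 (SD, n = 2), and Bcl11b, which was named after its values were seen. Foxp2 was marked with the peaks of replicate 2 alone and with the pooled list. Regulators of the forebrain and midbrain, regions in front of the neural tube's spinal part, were marked in 27 of 29 cases (93.1%, Fisher's exact test, adjusted p = 3.20e-18). Six3 and Vax2 were covered over 100% ± 0 (SD, n = 2), Vax1 over 99.0% ± 1.37 (SD, n = 2) and Foxg1, the forebrain factor, over 79.6% ± 7.15 (SD, n = 2), whereas Neurod6 and Hesx1 held no peak in either replicate.

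Regulators of lineages that do not arise from the neural tube were marked as well. The heart list had 17 of 18 members marked (94.4%, adjusted p = 5.27e-12), the endoderm list 21 of 24 (87.5%, adjusted p = 4.28e-13), the limb and skeleton list 25 of 29 (86.2%, adjusted p = 3.90e-15) and the kidney and gonad list 17 of 19 (89.5%, adjusted p = 3.16e-11), each by Fisher's exact test. The skeletal muscle list had 11 of 13 marked (84.6%, Fisher's exact test, adjusted p = 4.53e-07) and the blood list 14 of 22 (63.6%, adjusted p = 2.69e-06). These calls share genes with each other and with the neural lists. Of the 19 kidney and gonad members 11 also stand in another list, among them Pax2, Pax8 and Lhx1 of the spinal neuron list. The genes with high covered shares included Hand1 of the heart at 98.3% ± 2.42 (SD, n = 2), Pdx1 of the pancreas at 97.55% ± 1.29 (SD, n = 2), Foxf1 at 100% ± 0 (SD, n = 2), Pitx1 of the hindlimb at 98.9% ± 1.54 (SD, n = 2) and Six2 of kidney progenitors at 92.8% ± 0.721 (SD, n = 2). Gata4 stood at 92.0% ± 0.0566, Tbx5 at 91.5% ± 6.29, Nkx2-5 at 85.1% ± 7.20, Myod1 at 85.7% ± 1.31, Wt1 at 89.2% ± 13.4 and Tal1 at 80.7% ± 2.19 (SD, n = 2 for each). No peak was found within that window in either replicate at Gata1, the red cell factor, at Mef2c of the heart, at Myog and Myf6 of muscle, at Hnf4a and Hnf4g of the gut and liver, at Runx2 of bone, at Msgn1 or at Foxp3, although Runx2 was marked at another annotated transcript start. Regulators of the neural crest, which leaves the dorsal neural tube, were marked in 17 of 19 cases (89.5%, Fisher's exact test, adjusted p = 3.16e-11), with Tfap2c at 96.0% ± 2.36 (SD, n = 2) and no peak at Mitf in either replicate, although Mitf was marked with the pooled list.

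The contrast between neural and non-neural regulators did not pass its planned test, and whether it passed depended on the settings. The neural side held the neural tube progenitor and spinal neuron subtype lists, and the other side the heart, skeletal muscle, endoderm, blood, limb and skeleton, and kidney and gonad lists. The forebrain and midbrain list and the neural crest list were on neither side, except for members that a list in the contrast also holds. Leaving out the 15 genes that stand on both sides, 51 of 56 neural regulators (91.1%) and 79 of 99 non-neural regulators (79.8%) were marked. Non-neural minus neural was -11.3 percentage points (95% Newcombe interval -21.6 to 1.051) with a two-sided Fisher's exact p of 0.0733. With the peaks of replicate 2 alone the difference was -13.1 percentage points (Fisher's exact p = 0.0373), and with the peaks of replicate 1 alone it was -9.02 (Fisher's exact p = 0.137). Among genes with a CpG-rich promoter the direction turned, with 40 of 45 neural regulators (88.9%) and 42 of 46 non-neural regulators (91.3%) marked (Fisher's exact p = 0.739). Over the 11 alternatives the exact p ran from 0.0175 to 0.739, and 7 of them passed 0.05 with the neural share higher. A comparison of covered shares, not planned before the data were examined, gave a mean of 74.1% ± 27.3 (SD across genes, n = 56) for neural and 60.6% ± 37.6 (SD across genes, n = 99) for non-neural regulators, with a two-sided permutation p of 0.0182. It was not repeated among CpG-rich promoters. These made up 45 of the 56 neural and 46 of the 99 non-neural regulators, so this difference cannot be told apart from one of promoter class.

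**Figure D2:**
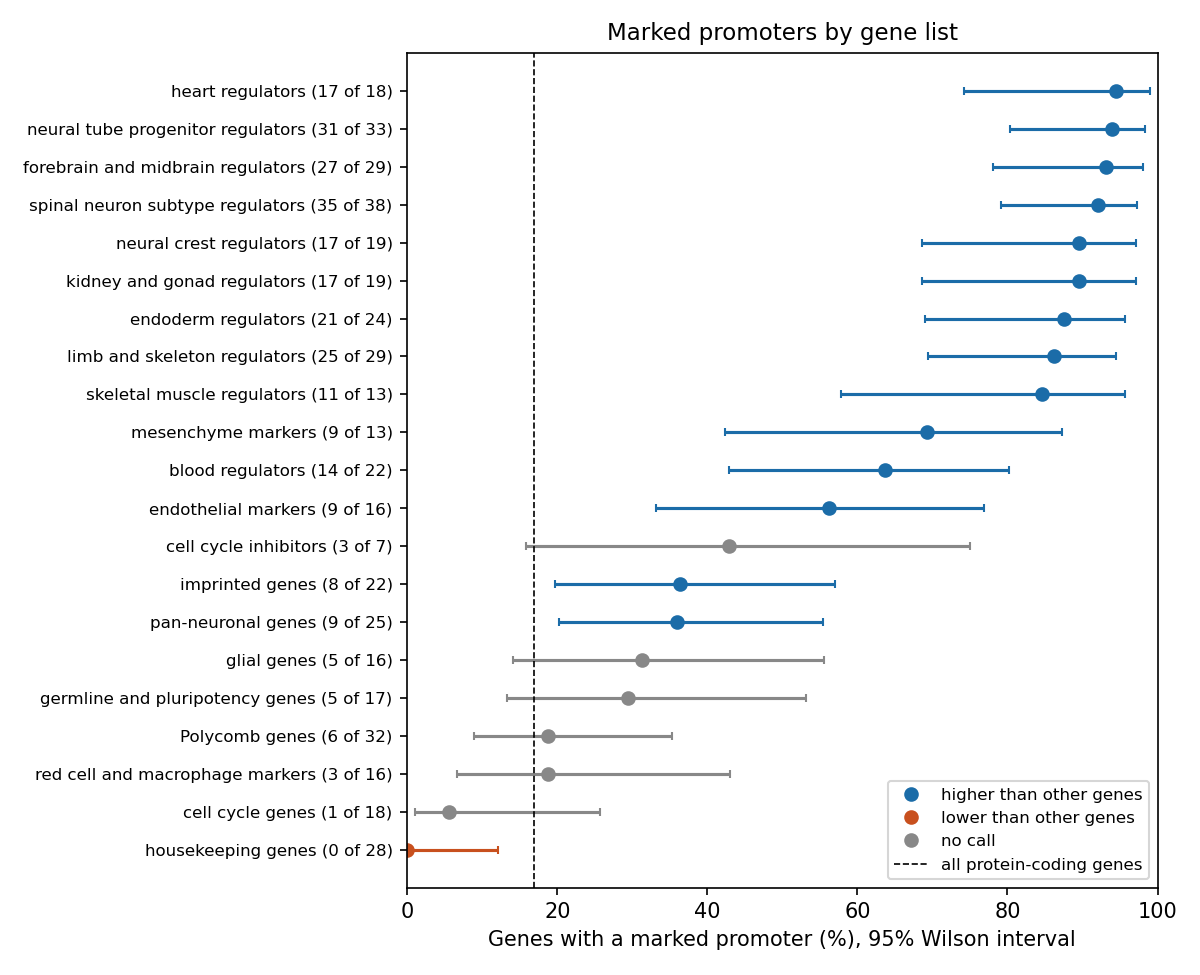
Share of each gene list with a marked promoter (horizontal axis, %) with its 95% Wilson interval, which covers counting error only; colour gives the call of Fisher's exact test against all other genes and the dashed line is the share over all protein-coding genes, 16.9%. The regulator lists of neural and other lineages lie at 63.6% or above, and the housekeeping list lies at 0.

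Genes in general use were rarely marked. None of the 28 housekeeping genes was marked, where a count of 0 allows a share of up to 10.7% by the limit of 3 counts and 12.1% by the 95% Wilson interval (Fisher's exact test, adjusted p = 0.0133). With the peaks of replicate 1 alone 1 of them was marked. Actb, Gapdh and Chmp2a held no peak in either replicate. That call ended when at least 25% of the promoter window had to be covered, with the peaks at or above the median signal, and with the pooled list. The 25% rule and the limit on signal can only remove marks. The count therefore stayed at 0 of 28 under both, and the end of the call there does not mean that housekeeping genes were marked. Of 76 ribosomal protein genes 1 was marked (1.32%, Fisher's exact test, adjusted p = 4.25e-05); it was Rpl3, at 46.0% ± 2.22 (SD, n = 2), named after its values were seen. With the peaks of replicate 1 alone 3 ribosomal protein genes were marked, which was also lower than other genes. Of 18 cell cycle genes 1 was marked, Ccnd1 of cyclin D1, at 26.3% ± 7.13 (SD, n = 2), while Aurka and Aurkb held no peak, and 2 were marked with the peaks of replicate 1 alone; this list did not differ from other genes by the test (Fisher's exact test, adjusted p = 0.367). Proteasome subunits were marked in 3 of 39 cases (7.69%, Fisher's exact test, adjusted p = 0.214). Of these Psmb8 and Psmb9, subunits of the immunoproteasome, stood at 90.1% ± 4.04 and 77.9% ± 0.240 (SD, n = 2), and were named after their values were seen. With the pooled list and among CpG-rich promoters the proteasome share was lower than that of other genes by the same test.

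Genes of differentiated neurons were divided. The 25 pan-neuronal genes had 9 marked members (36.0%, Fisher's exact test, adjusted p = 0.0336), led by the intermediate filament genes Ina at 70.5% ± 3.61 (SD, n = 2) and Nefl at 51.0% ± 6.77 (SD, n = 2) and by Crmp1 at 51.3% ± 19.8 (SD, n = 2). Dcx and Elavl4, genes of young neurons, held no peak in either replicate, and Tubb3, marked in replicate 1 and not in replicate 2, stood at 9.03% ± 12.8 (SD, n = 2). The call ended with the peaks at or above the median signal, with a −log10 q of at least 3, with pooled peaks that overlap a peak in each replicate list, with a promoter window of 500 bp and when at least 25% of the window had to be covered. Of 16 glial genes 5 were marked (31.2%, Fisher's exact test, adjusted p = 0.197), among them Sox10 at 64.4% ± 9.46, Pdgfra at 61.8% ± 1.55 and the myelin gene Mbp at 37.4% ± 3.15 (SD, n = 2 for each), while Aqp4 and Fabp7 held no peak. With the peaks of replicate 1 alone (8 marked), with the pooled list and with any annotated transcript start, the glial share was higher than that of other genes.

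Markers of other cell types that a dissected neural tube can hold gave mixed values. Endothelial markers were marked in 9 of 16 cases (56.2%, Fisher's exact test, adjusted p = 0.000632). Sox18 stood at 93.9% ± 0.495, Flt1 at 90.1% ± 0.269 and Sox7 at 89.5% ± 4.44 (SD, n = 2 for each), and Cdh5 and Egfl7 held no peak. Mesenchyme markers were marked in 9 of 13 cases (69.2%, Fisher's exact test, adjusted p = 7.51e-05), with Prrx1 at 89.4% ± 3.24, Foxc1 at 85.6% ± 1.65 and Twist1 at 78.4% ± 7.72 (SD, n = 2 for each) and no peak at Col3a1 or Dcn. Of these 13 markers 5 also stand in another list. Prrx1, Foxc1 and Twist1 are among them, as members of the limb and skeleton list, so this call is not separate from that one. Red cell and macrophage markers were marked in 3 of 16 cases (18.8%, Fisher's exact test, adjusted p = 0.760), namely Epor at 53.3% ± 1.94, Klf1 at 31.1% ± 13.3 and Fcgr3 at 23.5% ± 2.81 (SD, n = 2 for each). Fcgr3 was not marked when at least 25% of the window had to be covered. Gypa and Cd68 held no peak.

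Germline and pluripotency genes were marked in 5 of 17 cases (29.4%, Fisher's exact test, adjusted p = 0.213), with Prdm14 at 79.2% ± 6.07, Pou5f1, the gene of Oct4, at 52.8% ± 23.0 and Prdm1 at 52.4% ± 8.95 (SD, n = 2 for each), and no peak at Dazl or Dppa2, although Dazl was marked with the pooled list. Imprinted genes were marked in 8 of 22 cases (36.4%, Fisher's exact test, adjusted p = 0.0291), with Rasgrf1 at 98.2% ± 0.523, Phlda2 at 88.2% ± 8.22 and Grb10 at 85.8% ± 8.88 (SD, n = 2 for each) and none at Igf2r or Impact. That call ended with the pooled list and with replicate 2 alone, and among the 9 imprinted genes with a CpG-rich promoter the share was lower than that of other genes, with 1 marked (11.1%), a difference that did not pass the test (Fisher's exact test, adjusted p = 1). Of 32 Polycomb genes, a list that also holds the H3K27 demethylase genes Kdm6a and Kdm6b, 6 were marked (18.8%, Fisher's exact test, adjusted p = 0.812). These included Pcgf5 at 82.5% ± 1.202, Phf19 at 70.8% ± 1.80 and Cbx8 at 61.9% ± 5.33 (SD, n = 2 for each), with no peak at Cbx6, Cbx7 and further members. Cbx7 was marked at another annotated transcript start, and Cbx8 was not marked with a window of 500 bp or when at least 25% of the window had to be covered. Of 7 cell cycle inhibitors 3 were marked (42.9%, Fisher's exact test, adjusted p = 0.121). Cdkn2a, the locus of p16 and Arf, on chromosome 4 from 89274471 to 89294653, stood at 93.5% ± 0.0141, its neighbour Cdkn2b at 80.1% ± 11.8 and Cdkn2c at 25.8% ± 4.06 (SD, n = 2 for each), while Cdkn2d held no peak and Cdkn1b stood at 1.17% ± 1.65 (SD, n = 2). The inhibitors passed the test with a promoter window of 2.5 kb, with any annotated transcript start and with replicate 1 alone, where 5 were marked in each case.

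Over all 44 lists and families tested together, 30 had a higher marked share than other genes, 5 had a lower share and 9 did not differ (Fisher's exact test with Benjamini-Hochberg adjustment). Among the families of developmental transcription factors each of the 11 tested was higher with the main peak set, although the Klf family was not with the pooled list. All 14 Nkx genes, all 9 Pax genes, all 8 Lim-homeobox genes named Lhx and all 6 Irx genes were marked, with Fisher's exact adjusted p of 5.06e-11, 3.04e-07, 1.60e-06 and 4.61e-05. The families of Six1 to Six6 and of Gata1 to Gata6 had 5 of 6 members marked in each (Fisher's exact test, adjusted p = 0.00100 for both), the T-box genes named Tbx 9 of 13 (Fisher's exact test, adjusted p = 7.51e-05) and the Fox family 27 of 44 (Fisher's exact test, adjusted p = 1.38e-10). The Hox family had 22 of 39 (Fisher's exact test, adjusted p = 7.35e-08), the Sox family 10 of 19 (Fisher's exact test, adjusted p = 0.000632) and the Klf family 7 of 17 (Fisher's exact test, adjusted p = 0.0209). Zinc finger genes named Zfp, most of which lie outside these developmental families, were marked in 21 of 391 cases (5.37%, Fisher's exact test, adjusted p = 3.16e-11), which was lower than other genes.

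Most list calls were also made among CpG-rich promoters. Among genes with a CpG-rich promoter, 27 of the 44 lists and families had a higher share and 4 a lower one by Fisher's exact test with Benjamini-Hochberg adjustment. The progenitor regulators were then marked in 25 of 27 cases (92.6%), the neuron subtype regulators in 26 of 29 (89.7%) and the forebrain and midbrain regulators in all 17. Of the sets that were higher over all promoters and did not pass the test there, the Gata share was 100% (2 of 2) and the Klf share 42.9% (6 of 14), no smaller than over all promoters but over fewer members, and the imprinted share 11.1% (1 of 9). The proteasome share became lower than that of other genes, and the olfactory and vomeronasal receptors had too few CpG-rich promoters to test.

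Of the 15 widest domains, 7 held the 5′ end of a neural tube progenitor or spinal neuron subtype regulator, a count that was not tested against chance. Joining peaks at most 3 kb apart gave 11839 domains with a median width of 988 bp, of which 879 were at least 10 kb wide and held 45.9% of the covered bases, and 41 were at least 50 kb wide. The widest of the replicated list spanned 148 kb on chromosome 7 from 49613119 to 49761455. It held the 5′ ends of Dbx1, a factor of V0 interneuron progenitors, and of Htatip2, and was covered over 76.9% ± 3.09 (SD, n = 2). Olig2 and Olig1 lay in neighbouring domains on chromosome 16, of 92.4 kb (91155947 to 91248343, covered over 75.0% ± 1.54, SD, n = 2) and of 100.01 kb (91255777 to 91355788, covered over 65.5% ± 3.19, SD, n = 2). A domain of 104 kb on chromosome 7 from 139499963 to 139604072 held Nkx6-2. A domain of 92.8 kb on chromosome 2 from 33557823 to 33650623 held Lmx1b, and domains of 71.2 kb and 65.8 kb held Neurog1 on chromosome 13 and Prdm12 on chromosome 2. The 5′ part of the HoxC cluster lay in a domain of 96.3 kb on chromosome 15 from 102903019 to 102999346, with the 5′ ends of Hoxc13, Hoxc12, Hoxc11, Hoxc10, Hoxc5, Hoxc9, Hoxc8 and Hoxc6. The Hoxc6 promoter was not marked with replicate 2 alone, and neither the Hoxc6 nor the Hoxc8 promoter was with the peaks at or above the median signal or with a −log10 q of at least 3.

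Other members of the 15 widest domains held Cdh22, a cadherin gene, in 112 kb on chromosome 2, Nfix and G430095P16Rik in 105.04 kb on chromosome 8, Dmbx1 and 6430628N08Rik in 100.5 kb on chromosome 4, Pipox, whose promoter was not marked in replicate 2, in 77.2 kb on chromosome 11 and Ass1 in 73.7 kb on chromosome 2. A pair of domains on chromosome 4 held no protein-coding 5′ end. The first, of 99.9 kb from 117342433 to 117442298, lay over the body of Rnf220, and the second, of 65.8 kb from 148841943 to 148907734, over that of Casz1. Which domain was widest depended on the peak set: with the peaks of either replicate alone the domain over Rnf220 was, at 156 kb in replicate 2 and 148 kb in replicate 1, and with peaks at most 5 kb apart joined it was a 156 kb domain with Pipox and Sez6. Of the 15 widest domains, between 7 and 13 overlapped a domain among the 15 widest under each alternative.

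In the replicated list chromosome X had the smallest share of bases covered by peaks. Shares were taken over the length of each chromosome without its first 3 Mb. The replicated list covered 0.414% of X, against an autosomal median of 1.08% and an autosomal range of 0.581% to 2.15%, a ratio to the median of 0.385. X ranked 20 of 20 chromosomes, with an exact two-sided rank p of 0.1, the smallest this comparison allows, so that it could not pass 0.05. The replicates differed here. The ratio was 0.629 with the peaks of replicate 1, where X ranked 19, and 0.287 with those of replicate 2. Replicate 1 had 4383 peaks on X and replicate 2 had 1499, a ratio of 2.92, while the ratio on the 19 autosomes ran from 1.36 to 1.55. Of 948 protein-coding genes on X, 167 were marked in replicate 1 and 90 in replicate 2. The sexes were pooled, and neither the number of copies of X nor read depth entered these shares. They therefore do not measure the amount of the mark on X.

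**Figure D3:**
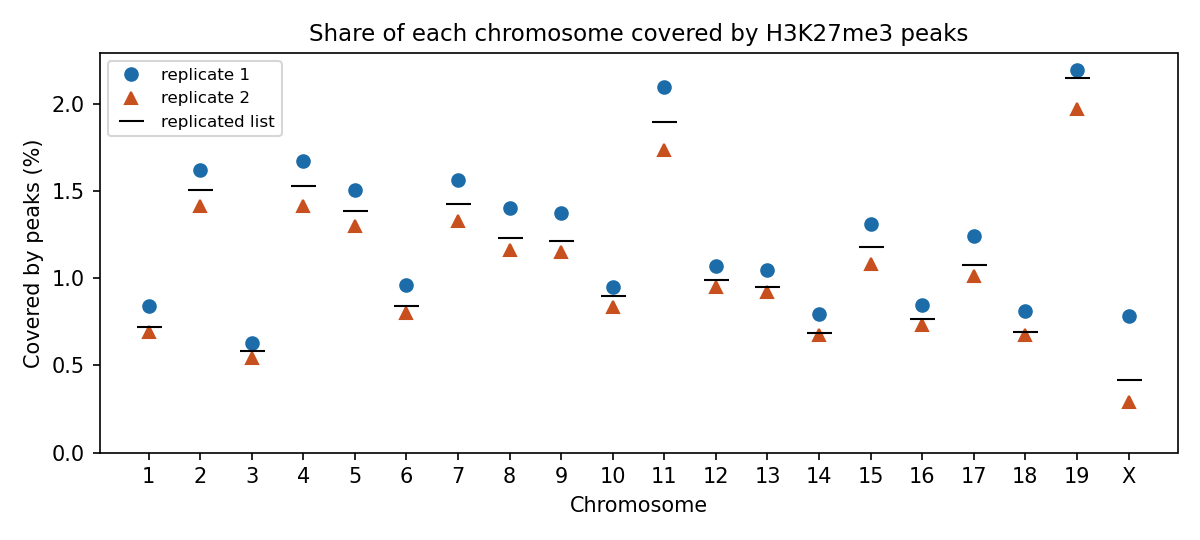
Share of each chromosome covered by peaks (vertical axis, %) for replicate 1, replicate 2 and the replicated list, by chromosome (horizontal axis). Replicate 1 lies above replicate 2 on every chromosome, and the gap is widest in proportion on X, with 0.783% against 0.290%.

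The replicates shared a minority of the peaks of replicate 1 and a majority of those of replicate 2. With an overlap of at least 1 bp, 38.2% of the peaks of replicate 1 met a peak of replicate 2, against 1.75% when the peaks of replicate 2 were shifted, and 54.6% of the peaks of replicate 2 met a peak of replicate 1, against 2.57%. The Jaccard index of the covered bases was 39.1%, against 0.617%. Each had a one-sided permutation p of 0.0099, the smallest that 100 shifts can give. Shared peaks were wider, with a median of 391 bp against 222 bp for unshared peaks in replicate 1 and of 401 bp against 235 bp in replicate 2. Across 257389 bins of 10 kb, which are not independent replicates, the covered bases of the replicates had a Spearman rho of 0.581. Most of these bins were empty in both replicates, and over the 39165 with a peak in either the rho was 0.466. Across the 28620 peaks of replicate 1 that met a peak of replicate 2, the authors' signal values had a Spearman rho of 0.503.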

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

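The alternatives were planned before the data were examined, except the pooled peaks that overlap a peak in each replicate list and the strongest peaks of replicate 1 in equal number to those of replicate 2, which were chosen after seeing the data. The count of marked promoters (2779 to 4761), the numbers of lists with higher (27 to 32) and lower (4 to 5) shares, the Hox difference (67.6 to 82.5 percentage points), the promoter share of covered bases (12.2% to 17.2%) and the overlap of the replicates kept their direction, and their side of the threshold where tested, under every alternative run for them. The neural difference, at -11.3 percentage points, passed the test at -16.3 with the peaks at or above the median signal, -14.3 with a −log10 q of at least 3, -13.3 with pooled peaks that overlap a peak in each replicate list, -14.5 and -13.8 with promoter windows of 500 bp and 2.5 kb and -15.5 with at least 25% of the window covered; Fisher's exact p over all its alternatives ran from 0.0175 to 0.739. Leaving out each replicate gave -13.1 to -9.02. Among CpG-rich promoters it reversed to 2.42, and the share of imprinted genes, at 11.1% (1 of 9), was below that of other genes without passing the test (Fisher's exact test, adjusted p = 1). The cause was not tested. The widest domain measured 155 kb with the pooled list, 102 kb and 156 kb with joining distances of 1 kb and 5 kb, and 148 to 156 kb when each replicate was left out; a shorter joining distance splits domains by construction. The X chromosome ratio ran from 0.287 to 0.629 when each replicate was left out, and was 0.594 with equal numbers of peaks. The rho of the replicates was 0.544 in 1 kb bins, 0.791 in 100 kb bins and 0.466 over bins with a peak. Of 138 named genes, between 1 and 7 changed their marked status under each alternative for peaks or promoters. No paired analysis was possible because the series has 1 group. Unknown depth leaves open whether a region without a peak lacks the mark or falls under the threshold.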

Other observations

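The counts of long non-coding RNA promoters and the tests on broadly used genes and on the X peaks were chosen after the main results were seen. Genes of the Wnt, Bmp and Fgf families also carried the mark. Of 19 Wnt ligands 18 were marked (94.7%, Fisher's exact test, adjusted p = 1.05e-12), with Wnt8a the exception. Wnt1 and Wnt3a, signals of the roof plate, were covered over 99.1% ± 1.27 and 98.4% ± 0.0424 (SD, n = 2) of the 2.5 kb either side of their 5′ ends. Of 11 genes named Bmp, among them the protease gene Bmp1, 7 were marked (63.6%, Fisher's exact test, adjusted p = 0.00100), with Bmp7 at 98.0% ± 2.79 (SD, n = 2). Of 22 genes named Fgf 12 were marked (54.5%, Fisher's exact test, adjusted p = 0.000112), with Fgf8 at 98.7% ± 1.78 (SD, n = 2). The Fgf genes include Fgf11 to Fgf14, whose products are not secreted. Part of the potassium channel and glutamate receptor genes tested was also marked. Voltage-gated potassium channels named Kcna, Kcnb or Kcnc were marked in 11 of 14 cases (78.6%, Fisher's exact test, adjusted p = 1.60e-06), led by Kcnc1 at 98.2% ± 2.53 (SD, n = 2), and glutamate receptors in 9 of 16 (56.2%, Fisher's exact test, adjusted p = 0.000632). Within the glutamate receptors the mark was found at 6 of the 7 NMDA receptor genes, all but Grin2d, such as Grin2c at 94.99% ± 4.14 (SD, n = 2), and at none of the 4 AMPA receptor genes Gria1 to Gria4. Of the 5 kainate receptor genes 3 were marked, Grik1, Grik3 and Grik4, and the difference between these classes was not tested. These members were named after their values were seen. Large families of sensory genes were rarely marked. Of 1092 olfactory receptor genes 1 was marked, Olfr94 (0.0916%, Fisher's exact test, adjusted p = 9.14e-87). With the peaks of replicate 1 alone 8 were marked and with those of replicate 2 alone 2, both also lower than other genes. Of 326 vomeronasal receptor genes 0 were marked, where a count of 0 allows up to 0.920% by the limit of 3 counts and 1.16% by the 95% Wilson interval (Fisher's exact test, adjusted p = 1.78e-25). Keratins were marked in 10 of 49 cases (20.4%, Fisher's exact test, adjusted p = 0.592) and clustered protocadherins in 5 of 56 (8.93%, Fisher's exact test, adjusted p = 0.179).

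The highest signal value of the replicated list, 12.66 in the authors' unit, was at Adra2c, the gene of an adrenergic receptor, in a peak of 8303 bp on chromosome 5 from 35276167 to 35284469. The next lay at Fam43b, in a peak that overlapped Gjc2 without its 5′ end, and at Wnt3a and Olig1. Promoters of long non-coding RNAs were marked in 977 of 9241 cases (10.6%, 95% Wilson interval 9.96% to 11.2%, counting error only). Within 5 kb of a marked protein-coding 5′ end the count was 470 of 557 (84.4%), within 5 kb of an unmarked one 46 of 1680 (2.74%), and farther away 461 of 7004 (6.58%). The windows of 1 kb either side of close 5′ ends share bases, so a single peak can mark both genes. Part of the difference within 5 kb follows from that, and pairs with separate windows were not counted apart.

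Genes that progenitors use broadly were compared with the progenitor and neuron subtype regulators. A list of 34 broadly used genes, such as Vim, Msi1 and Notch1, was written after the fixed lists had been seen and before the values of its members were. Of these 4 were marked (11.8%: Pou3f3, Insm1, Lin28a and Ccnd2), against 16.9% of all other genes, a difference that did not pass the test (Fisher's exact p = 0.645), nor did it among CpG-rich promoters (9.09% against 19.9%, Fisher's exact p = 0.287). The regulators other than Sox1, Sox2, Sox3, Hes1 and Hes5 were marked in 63 of 66 cases (95.5%), 83.7 percentage points above the broad list (Fisher's exact p = 7.24e-18); that choice was made after the marks were seen, and with these 5 kept in the count was 66 of 71 and the difference 81.2. Membership of the CpG-rich class and the 1 bp overlap rule were argued against as the whole of this difference. It was 85.0 percentage points among CpG-rich promoters and 88.1 with at least 25% of the window covered. CpG density within that class was not matched, so CpG content beyond the class stays untested. An effect of breadth of use cannot be told apart from the high share of the regulators alone, since any list near the share of all genes gives a similar difference, and expression was not measured here.

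Replicate 1 had 2.92 times as many peaks on X as replicate 2, above the highest autosomal ratio of 1.55. A lower threshold in replicate 1 was argued against, since with equal numbers of peaks the X ratio was 2.01 against a highest autosomal ratio of 1.02. A few loci were argued against too, since without the 5 bins of 1 Mb with the largest excess the ratio was 3.02. The different input files behind the peak calls cannot be told apart from a difference between the samples. The signal of shared X peaks, replicate 1 over replicate 2, was 1.09 times that of shared autosomal peaks, which either could give. The 95% bootstrap interval of 1.08 to 1.12 resamples peaks, which are clustered and not independent replicates, so it gives no spread between samples. A different share of female embryos, whose inactive X carries H3K27me3, may also give the excess of X peaks. The labels name only pooled sexes, so this stays untested.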
